A study of Homo sapiens with 12 samples.

How the data were processed

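RNA was sequenced from 12 libraries of AC16, an established human cell line made by fusing cells of adult ventricular heart tissue with transformed fibroblasts. Per the labels' protocols, cells in serum-free medium received either a negative control siRNA or an siRNA against EP300 through the jetPRIME reagent, and 12 h later some were exposed to hydrogen peroxide (H2O2) for 1 h at a labelled 200 mM, a unit that is uncertain and may stand for a lower dose. Complete medium then replaced the oxidant, RNA was isolated with Trizol after 48 h, and libraries followed the procedure of BGI. Samples were grouped by the siRNA and the H2O2 named in their titles, which gave 4 groups of 3 libraries. A treatment field of the labels names MLF1 instead of EP300 for the same 6 samples, so both genes were examined in every library before any comparison.

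The authors deposited 1 table of estimated counts per gene symbol and 1 table of FPKM, which scales fragments to gene length and library total, for the same 17197 symbols. Per the submitters' processing notes, HISAT and Bowtie2 were used with the GRCh38.p13 build; their versions and roles, the counting program, the gene annotation, the strand setting and any gene filter are not given in the sources used here. Between 12.0% and 13.8% of the estimated counts in a library were not whole numbers, and they were rounded before testing. The deposited counts were not scaled between libraries and summed to between 16081437 and 19033679 per library. The 10 most abundant genes held 3.82% to 4.28% of a library's counts. Neither table held mitochondrially encoded genes under the symbols searched. Genes that share reads with near-identical copies, and genes that overlap others, carry the uncertainty of an unstated counting rule.

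Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (glmQLFit, glmQLFTest), TMM scaling factors and 1 mean per group fitted to all 12 libraries. Genes were kept by filterByExpr, which left 13171. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05; each adjusted p given for a gene comes from this test unless another is named. The comparisons were EP300 siRNA against control siRNA without and with H2O2, H2O2 against none with control and with EP300 siRNA, and the interaction, which is the EP300 siRNA effect with H2O2 minus that without. Levels are CPM, counts relative to the TMM-scaled library total, with the SD over 3 libraries. Log2 fold changes carry the standard error of the fit. TMM factors ran from 0.969 to 1.05, and the common dispersion was 0.00451, a biological coefficient of variation of 6.72%.

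Counts were simulated from the sizes of all 12 libraries and each gene's mean over them. Genes were drawn independently, so differences that real libraries share across genes are absent. For EP300 siRNA without H2O2, with 13059 genes tested, the test recovered 76% of 100 genes changed 1.5-fold and 93% of 100 genes changed 2-fold. It called 13 unchanged genes. For a simulated interaction over 13054 genes these values were 68%, 89% and 10. Far fewer genes were changed than the real EP300 siRNA comparisons called, so recovery and false calls may differ there. Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.78 to 18.1 over genes with at least 20 counts, so no library was treated as a repeat of another.

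Lists of genes were fixed before the data were examined. There were 27: NRF2 antioxidant targets, p53 targets, mitosis, DNA replication, NF-kB inflammatory targets, interferon-stimulated genes, unfolded protein response and ATF4 targets, heat shock proteins, hypoxia and HIF targets, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, cholesterol synthesis, ferroptosis regulators, apoptosis regulators, autophagy and lysosome genes, extracellular matrix and fibroblast markers, TGF-beta and YAP targets, cardiomyocyte markers, immediate early genes, lysine acetyltransferases and deacetylases, senescence-associated secreted factors, replication-dependent histones, and markers of endothelial, epithelial, leukocyte and smooth muscle cells. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with members counted after adjustment over all genes and over the list alone. Estimating the correlation per list, and fry, were the alternatives.

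Genes named in the text follow a rule also fixed beforehand. It takes EP300, MLF1 and CREBBP; the 8 largest rises and 8 largest falls of each two-group comparison among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries; the 5 largest differences each way in the interaction; and up to 4 members with the smallest adjusted p of each list described. Symbols of pseudogene, antisense, clone or noncoding type were left out, and a few genes that the rule names are not reported here.

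Agreement between comparisons was measured by correlations of log2 fold changes across genes, which are not independent replicates and get no p-value. Where comparisons shared libraries, 20 simulations of unchanged groups gave the value that the shared libraries alone produce. Alternatives fixed beforehand were median-of-ratios size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, at least 50 counts in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with an FPKM of at least 1 in 3 libraries or without that filter, a 2-fold minimum, only the 2 groups compared, and leaving out each library. Alternatives chosen after seeing the data were offsets that remove each library's smooth trend on transcript length and GC content (loess, span 0.3), leaving out the pair of libraries farthest out on the axis that follows length, and Spearman in place of Pearson correlation.

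Transcript lengths, GC content, sequences and coordinates came from GENCODE 29 (GRCh38), to which 16982 of the 17197 symbols were matched, 16643 by name and 339 by a current or older symbol. Words of 7 bases in coding sequences and 3′ UTRs were scored against log2 fold changes, limited to 3 either way, with 999 permutations and a family-wise p whose smallest value is 0.001. These steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.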

Results

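Transcript levels were measured by RNA sequencing in AC16 human cardiomyocyte-derived cells in a layout that crossed EP300 siRNA with H2O2, an oxidant. EP300 encodes p300, a lysine acetyltransferase and transcriptional coactivator whose molecular role in this line is the stated subject of the series. The 12 libraries formed 4 groups of 3: control siRNA (siNC, libraries 1 to 3), EP300 siRNA (siEP300, 4 to 6), control siRNA with H2O2 (siNC.H2O2, 7 to 9) and EP300 siRNA with H2O2 (siEP300.H2O2, 10 to 12). Estimated counts summed to 18113117, 18489745 and 18144979 in siNC and to 18374277, 17623688 and 18407350 in siEP300. They summed to 19033679, 16081437 and 18669147 in siNC.H2O2 and to 18411208, 17925774 and 18730365 in siEP300.H2O2. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

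The first principal component of log2 CPM held 56.9% of the variance and separated the siRNAs, with control siRNA libraries at -30.88 or lower and EP300 siRNA libraries at 32.4 or higher. The second component held 21.9% and separated H2O2, with untreated libraries at 19.28 or higher and treated ones at -15.42 or lower. Libraries of 1 group also differed along an axis that held 55.5% of the variance within groups, and its gene loadings followed transcript length with a rank correlation of 0.72 and GC content with one of -0.49 across genes. On this axis siNC library 1 scored 11.4 and siNC.H2O2 library 7 scored -11.7, and the 3 siEP300 libraries lay between -1.16 and 1.59.

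EP300, at chromosome 22, positions 41091786 to 41180079 on the plus strand of GRCh38, fell with its siRNA. Its level was 101, 69.1 and 80.2 CPM in siNC (83.3 ± 16.1, SD, n = 3) and 36.3, 36.8 and 36.7 CPM in siEP300 (36.6 ± 0.31), a log2 fold change of -1.19 ± 0.14 (SE, edgeR adjusted p = 3.6e-06). With H2O2 it was 59.9, 80.4 and 89.9 CPM in siNC.H2O2 (76.7 ± 15.3) and 30.1, 26.9 and 26.5 CPM in siEP300.H2O2 (27.8 ± 2.01), a log2 fold change of -1.46 ± 0.14 (edgeR adjusted p = 5.9e-07). The share of EP300 left was 43.9% without and 36.3% with H2O2. H2O2 moved EP300 by -0.12 with control siRNA (edgeR adjusted p = 0.52) and by -0.40 with EP300 siRNA (edgeR adjusted p = 0.053), neither past the threshold, and 6 alternatives put the second value past it.

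MLF1, the gene named in the conflicting treatment field, lies at chromosome 3, positions 158571163 to 158607252 on the plus strand. It stood at 47.5 ± 2.47 CPM in siNC, 40.9 ± 1.94 in siEP300, 51.4 ± 0.29 in siNC.H2O2 and 42.2 ± 0.66 in siEP300.H2O2 (SD, n = 3). Its log2 fold changes with EP300 siRNA were -0.22 ± 0.06 without and -0.29 ± 0.06 with H2O2 (SE, edgeR adjusted p = 0.0052 and 0.00069), leaving 86.1% and 82.1%. CREBBP, the closest paralog of EP300, at chromosome 16, positions 3725054 to 3880726 on the minus strand, rose from 103 ± 14.3 to 143 ± 3.29 CPM without H2O2 and from 91.6 ± 7.39 to 130 ± 9.98 CPM with it. Its log2 fold changes were 0.48 ± 0.09 and 0.50 ± 0.09 (SE, edgeR adjusted p = 0.00024 and 0.00019).

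**Figure D1:**
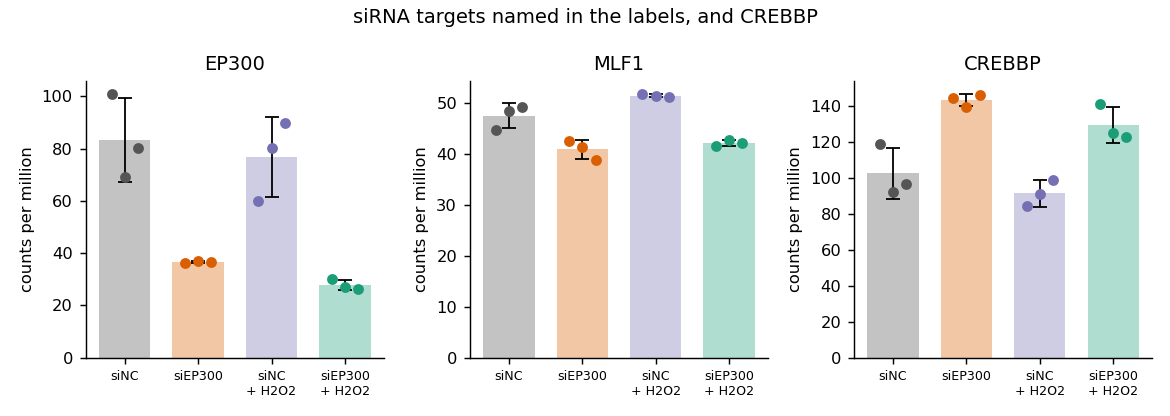
Levels of EP300, MLF1 and CREBBP in CPM for each of the 12 libraries (points), with the mean (bars) and SD (error bars) of the 3 libraries per group. EP300 was 43.9% of its control level with EP300 siRNA and 36.3% with EP300 siRNA and H2O2, MLF1 was 86.1% and 82.1%, and CREBBP was above its control level in both.

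The first comparison asked what EP300 siRNA changed in cells without H2O2. The cystine importer SLC7A11, the immediate early transcription factors EGR1 and FOS and the connective tissue growth factor CCN2 rose, while the cell cycle inhibitor CDKN1A and the chromatin remodeller subunit SMARCD3 fell. GLT8D2, a putative glycosyltransferase, rose from 7.87 ± 0.70 to 60.5 ± 3.73 CPM (log2 fold change 2.94 ± 0.08), and INHBE, an activin subunit, from 1.47 ± 0.27 to 11.8 ± 0.997 CPM (2.997 ± 0.16). SLC7A11 rose from 20 ± 3.37 to 110 ± 4.57 CPM (2.46 ± 0.12). Further large rises were SCN9A, a sodium channel (2.37), TFPI2, a protease inhibitor (2.16), AGTR1, the angiotensin II receptor (2.13), CCN2 (2.06) and CPED1 (2.05), all with edgeR adjusted p of 1.1e-08 or lower.

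The largest falls without H2O2 were the annexin genes ANXA8 (log2 fold change -3.33 ± 0.12, from 53.9 ± 3.90 to 5.35 ± 0.66 CPM) and ANXA8L1 (-3.29 ± 0.15), near-identical copies whose reads may be divided between them arbitrarily. VWA1, an extracellular matrix protein, fell by 3.23 on the log2 scale, and SMARCD3, a heart-enriched subunit of the SWI/SNF chromatin remodeller, fell by 3.22, from 21.3 ± 1.86 to 2.28 ± 0.05 CPM. RIPOR3 fell by 3.06, COLEC12, a scavenger receptor, by 3.02 and SOCS1, an inhibitor of cytokine signalling, by 2.94, the last from 8.94 ± 1.58 to 1.16 ± 0.26 CPM. The log2 fold change of SHISAL1 was -3.005. All 8 had edgeR adjusted p of 5.7e-08 or lower.

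Among unfolded protein response and ATF4 targets, 18 of 25 measured members rose and 4 fell without H2O2 (18 and 4 adjusted over the list alone; camera adjusted p = 3.6e-07; adjusted p = 0.29 with an estimated correlation). They included PSAT1 (log2 fold change 1.95 ± 0.06) and ASNS (1.45 ± 0.06), enzymes of serine and asparagine synthesis, ALDH1L2 of mitochondrial folate metabolism (1.75 ± 0.10) and CHAC1, a glutathione-degrading enzyme (1.60 ± 0.10). Of 28 immediate early genes 16 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.29 with an estimated correlation). The transcription factors EGR1 (1.81 ± 0.08) and FOS (1.76 ± 0.09) rose with IER2 (1.62 ± 0.09) and the phosphatase DUSP1 (1.02 ± 0.07). NRF2 antioxidant targets had 15 of 24 higher and 4 lower (15 and 4 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.29 with an estimated correlation). The quinone reductase NQO1 (1.27 ± 0.06), malic enzyme ME1 (1.36 ± 0.09) and SLC7A11 rose and glutathione reductase GSR fell by 0.71.

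Mitosis genes rose in 20 of 30 and fell in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.29 with an estimated correlation). The spindle motor CENPE (0.93 ± 0.09), the hyaluronan receptor HMMR (0.73 ± 0.06), the kinesin KIF20A (0.58 ± 0.06) and the checkpoint kinase BUB1 (0.53 ± 0.05) rose. Interferon-stimulated genes rose in 16 of 25 and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 0.0054; adjusted p = 0.42 with an estimated correlation). IFI44 (0.93 ± 0.07), the RNA sensor IFIH1 (0.81 ± 0.08) and OAS3 (0.70 ± 0.07) rose. TGF-beta and YAP targets split, 12 of 24 higher and 8 lower (12 and 9 adjusted over the list alone; camera adjusted p = 0.0059; adjusted p = 0.29 with an estimated correlation). CCN2, CCN1 (1.54 ± 0.06) and tissue factor F3 (1.51 ± 0.06) rose.

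Extracellular matrix and fibroblast markers also went both ways, 13 of 28 higher and 8 lower (15 and 8 adjusted over the list alone; camera adjusted p = 0.47). The collagen COL4A1 (1.90 ± 0.11) and the proteoglycan VCAN (1.77 ± 0.15) rose, and the gelatinase MMP2 (-1.75 ± 0.08) and lumican LUM (-0.95 ± 0.08) fell. In the p53 target list 9 of 25 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.65), and with deposited FPKM these counts were 8 and 8. CDKN1A, the p53-induced cell cycle inhibitor at chromosome 6, positions 36676460 to 36687339 on the plus strand, fell by 1.90, and PHLDA3 fell by 0.71, while the sestrin SESN2 (1.14 ± 0.08) and the DNA repair gene XPC (0.72 ± 0.08) rose. Of 30 cardiomyocyte markers among the deposited symbols, only 14 passed the filter on low counts. Of these 14 measured markers 3 rose and 9 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.13). The intermediate filament DES (-1.87 ± 0.19), the gap junction protein GJA1 (-0.91 ± 0.08), the transcription factor GATA6 (-0.82 ± 0.06) and creatine kinase CKB (-0.76 ± 0.10) fell. Fry, which asks only whether a list's genes move on balance in 1 direction, gave that list an adjusted p of 3.3e-06. Markers of other cell types fell in the same comparison, 4 of 7 endothelial (1 rose; 4 and 1 adjusted over the list alone; camera adjusted p = 0.47, fry adjusted p = 0.00011), 3 of 7 epithelial (fry adjusted p = 0.00067) and 2 of 3 leukocyte markers (fry adjusted p = 0.0033). Of 10 smooth muscle markers 5 were higher and 3 lower, with no net move called (5 and 3 adjusted over the list alone; camera adjusted p = 0.82, fry adjusted p = 0.47; mean 0.0056, median 0.25, and median -0.01 with deposited FPKM).

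In all, 8103 of 13171 genes (61.5%) passed the edgeR test without H2O2, 3964 higher and 4139 lower with EP300 siRNA, and 1300 of them changed at least 2-fold, 386 higher and 914 lower. With deposited FPKM (pseudocount 1) 3063 genes were higher and 4317 lower. The median log2 fold change over the genes tested was -0.049 with FPKM, against -0.0042 in the edgeR fit. Directions in this and the other comparisons are relative to the bulk of genes, on which TMM scaling rests. A shift shared by most genes would not be seen. Fold changes followed GC content with a rank correlation of -0.36 and transcript length with one of 0.20 across genes.

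The second comparison asked the same in H2O2-treated cells. The immediate early factor EGR1, the interferon-stimulated IFI44 and CCN2 were higher with EP300 siRNA. The hypoxia-induced CA9 and lactate dehydrogenase LDHA were lower, as were the collagen COL6A1 and the cardiac transcription factors GATA4 and GATA6. Hyaluronan synthase HAS2 rose from 3.73 ± 0.24 to 22.6 ± 2.64 CPM (log2 fold change 2.60 ± 0.12) and CD274, the checkpoint ligand PD-L1, from 15.96 ± 1.09 to 70.0 ± 6.08 CPM (2.13 ± 0.08). GLT8D2 (2.65), the keratin-associated KRTAP2-3 (2.32), CCN2 (2.21), CPED1 (2.19), EGR1 (2.13) and the lysine methyltransferase SETD7 (2.13) rose as well, all 8 with edgeR adjusted p of 1.4e-08 or lower.

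Falls in H2O2-treated cells were led by ADAMTS15, a matrix-degrading protease, from 19.7 ± 0.39 to 1.86 ± 0.37 CPM (log2 fold change -3.40 ± 0.12). SLC12A8, a nicotinamide mononucleotide transporter, fell by 3.06 (from 83.6 ± 2.25 to 10.1 ± 0.84 CPM), PTGES, a prostaglandin E synthase, by 3.06, and the hypoxia-induced carbonic anhydrase CA9 by 2.97 (from 53.2 ± 6.86 to 6.76 ± 1.21 CPM). RIPOR3 fell by 3.27, SOCS1 by 3.21, COLEC12 by 3.08 and ANXA8 by 2.80, and these 8 had edgeR adjusted p of 9.9e-09 or lower.

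Hypoxia and HIF targets fell in 16 of 24 and rose in 3 with H2O2 (16 and 3 adjusted over the list alone; camera adjusted p = 0.00035; adjusted p = 0.39 with an estimated correlation). Beside CA9 they included NDRG1 (-1.34 ± 0.06), the mitophagy receptor BNIP3L (-1.03 ± 0.06) and the glycolytic regulator PFKFB3 (-0.93 ± 0.06). Glycolysis genes fell in 13 of 19 and rose in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.0059; adjusted p = 0.52 with an estimated correlation). Lactate dehydrogenase LDHA (-1.07 ± 0.05), hexokinase HK1 (-0.67 ± 0.05), the lactate exporter SLC16A3 (-0.53 ± 0.06) and enolase ENO1 (-0.52 ± 0.06) fell. Extracellular matrix and fibroblast markers fell in 13 of 28 and rose in 6 (13 and 7 adjusted over the list alone; camera adjusted p = 0.037; adjusted p = 0.61 with an estimated correlation). MMP2 (-2.06 ± 0.08), the collagens COL6A1 (-1.03 ± 0.06) and COL6A2 (-0.80 ± 0.06) and the growth factor receptor PDGFRB (-1.14 ± 0.08) fell.

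Cardiomyocyte markers fell in 8 of 14 and rose in 2 (8 and 3 adjusted over the list alone; camera adjusted p = 0.072; fry adjusted p = 4.3e-06). The cardiac transcription factors GATA6 (-1.03 ± 0.06) and GATA4 (-0.68 ± 0.09), GJA1 (-1.01 ± 0.08) and CKB (-0.57 ± 0.10) fell. Of 7 measured endothelial markers 6 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.073, fry adjusted p = 5.4e-06). TIE1 (-2.35 ± 0.26), EGFL7 (-1.77 ± 0.14) and KDR (-1.16 ± 0.16) fell, and TEK (1.28 ± 0.15) rose. Of 7 epithelial markers 4 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.38, fry adjusted p = 0.00062). Leukocyte markers fell in 2 of 3 and rose in 1 (camera adjusted p = 0.71, fry adjusted p = 0.048), and smooth muscle markers rose in 5 of 10 and fell in 3 (camera adjusted p = 0.71, fry adjusted p = 0.085).

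DNA replication genes rose in 23 of 38 and fell in 5 (23 and 5 adjusted over the list alone; camera adjusted p = 0.0059; adjusted p = 0.39 with an estimated correlation). The ribonucleotide reductase subunit RRM1 (0.73 ± 0.05), GINS1 (0.72 ± 0.06) and the licensing factor CDC6 (0.63 ± 0.05) rose, while cyclin E CCNE1 fell by 2.54. Interferon-stimulated genes rose in 18 of 25 and fell in 1 (18 and 2 adjusted over the list alone; camera adjusted p = 0.0014; adjusted p = 0.39 with an estimated correlation). IFI44 (1.23 ± 0.08), OAS3 and IFIH1 (both 0.89) rose. Immediate early genes rose in 14 of 28 and fell in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.39 with an estimated correlation). EGR1, FOS (2.12 ± 0.10) and IER2 (1.44 ± 0.09) rose and the phosphatase DUSP4 fell by 0.82. NRF2 targets rose in 14 of 24 and fell in 5 (14 and 5 adjusted over the list alone; camera adjusted p = 0.022; adjusted p = 0.39 with an estimated correlation). SLC7A11 (1.66 ± 0.13), NQO1 (1.28 ± 0.06) and ME1 (0.96 ± 0.09) were higher and GSR (-0.74 ± 0.06) was lower.

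Unfolded protein response and ATF4 targets rose in 13 of 25 and fell in 7 (13 and 8 adjusted over the list alone; camera adjusted p = 0.037; adjusted p = 0.61 with an estimated correlation). PSAT1 (1.47 ± 0.06), ASNS (1.04 ± 0.07), the stress factor DDIT3 (1.16 ± 0.10) and TRIB3 (1.06 ± 0.09) rose. TGF-beta and YAP targets went both ways, 10 of 24 higher and 9 lower (11 and 9 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.39 with an estimated correlation). CCN1 (1.59 ± 0.06) and F3 (1.40 ± 0.06) were higher and the matrix protein TGFBI (-1.10 ± 0.05) was lower. Of 25 p53 targets 12 rose and 6 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.69). The apoptosis gene PMAIP1 (0.54 ± 0.07) rose and CDKN1A (-1.51 ± 0.08), SESN1 (-0.53 ± 0.07) and PLK2 (-0.45 ± 0.06) fell. In H2O2-treated cells 7776 genes (59.0%) passed the edgeR test, 3742 higher and 4034 lower, and 1240 changed at least 2-fold, 345 higher and 895 lower. With deposited FPKM (pseudocount 1) 3352 genes were higher and 3770 lower. Fold changes followed GC content with a rank correlation of -0.32 across genes.

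**Figure D2:**
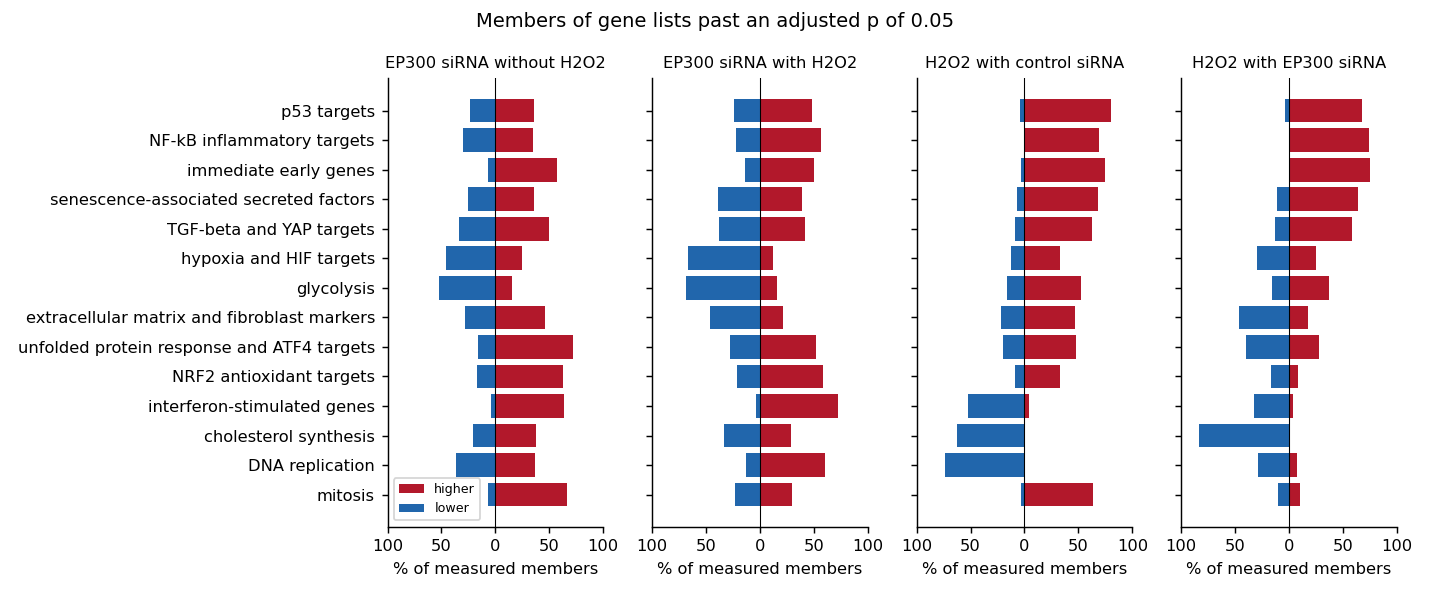
Percent of the measured members of 14 gene lists that were higher (red) or lower (blue) in each two-group comparison, by edgeR's adjusted p. Without H2O2, EP300 siRNA raised 18 of 25 unfolded protein response and ATF4 targets, and H2O2 with control siRNA raised 20 of 25 p53 targets and lowered 28 of 38 DNA replication genes.

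EP300 siRNA effects with and without H2O2, which share no library, were alike across the 13171 genes, with a Pearson correlation of 0.85 and a Spearman correlation of 0.87. The slope of the effect with H2O2 on that without was 0.82. Noise in the effect without H2O2 lowers such a slope, so it is not a measure of a weaker effect. Called genes overlapped: 3076 were higher in both against 1126 for independent lists, 3305 were lower in both against 1268, and 34 and 14 were called in opposite directions. Keeping genes of any count lowered the Pearson correlation to 0.46.

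The third comparison asked what H2O2 changed in cells with control siRNA. The cytokines GDF15 and IL1B, most p53 targets, the phosphatase DUSP6 and cyclin D1 rose, and most DNA replication genes fell. GDF15, a stress-induced cytokine at chromosome 19, positions 18374731 to 18389176 on the plus strand, rose from 1.54 ± 0.43 to 31.4 ± 0.79 CPM (log2 fold change 4.34 ± 0.18), and the inflammatory cytokine IL1B from 7.82 ± 1.22 to 80.5 ± 5.45 CPM (3.36 ± 0.11). CCND1, which encodes cyclin D1 at chromosome 11, positions 69641087 to 69654474 on the plus strand, rose from 54.2 ± 5.08 to 318 ± 10.7 CPM (2.55 ± 0.07). IL24, a cytokine (3.02), G0S2, a lipase inhibitor (2.79), transglutaminase TGM2 (2.77), the ERK phosphatase DUSP6 (2.47) and the protease inhibitor SERPINB2 (2.31) followed, all 8 with edgeR adjusted p of 1.8e-09 or lower.

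The largest falls with control siRNA were smaller. The p38 kinase activator MAP2K6 fell by 2.32 on the log2 scale, from 17.4 ± 2.16 to 3.50 ± 0.50 CPM, and SFT2D3 fell by 2.19 (edgeR adjusted p = 0.0024, 0.072 with DESeq2). AKR1C3, an aldo-keto reductase, fell by 1.67, OLFML3 and the actin-associated SYNPO both by 1.61, GASK1B by 1.59, SERPINF1, a secreted antiangiogenic factor, by 1.55 and C1QL4 by 1.53, these 6 with edgeR adjusted p of 2.7e-06 or lower.

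Of 28 immediate early genes 21 rose and 1 fell with H2O2 (23 and 1 adjusted over the list alone; camera adjusted p = 5.1e-26, 0.0050 with an estimated correlation). The phosphatases DUSP6, DUSP5 (1.94 ± 0.09) and DUSP4 (1.55 ± 0.06) and the transcription factor FOSL1 (2.24 ± 0.09) rose. Among p53 targets 20 of 25 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 6.3e-23, 0.00060 with an estimated correlation). GDF15, CDKN1A (1.68 ± 0.08), the nuclease AEN (1.56 ± 0.06) and the antiproliferative BTG2 (1.45 ± 0.10) rose. Senescence-associated secreted factors, which share GDF15, CDKN1A and IL1B with other lists, rose in 19 of 28 and fell in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 4.3e-23, 0.0060 with an estimated correlation). NF-kB inflammatory targets rose in 16 of 23 and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 9.5e-15, 0.0012 with an estimated correlation). IL11 (2.02 ± 0.11), the inhibitor TNFAIP3 (1.15 ± 0.07) and the adhesion molecule ICAM1 (0.85 ± 0.06) rose beside IL1B. TGF-beta and YAP targets rose in 15 of 24 and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 4.5e-15, 0.0050 with an estimated correlation). ANKRD1 (1.68 ± 0.08), F3 (1.49 ± 0.06) and thrombospondin THBS1 (1.38 ± 0.08) rose.

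DNA replication genes fell in 28 of 38 and none rose with H2O2 (28 and 0 adjusted over the list alone; camera adjusted p = 6.1e-14, 0.014 with an estimated correlation). Cyclin E CCNE2 (-1.10 ± 0.09) and the helicase subunits MCM5 (-0.61 ± 0.05) and MCM6 (-0.57 ± 0.05) fell. Mitosis genes rose in 19 of 30 and fell in 1 (19 and 2 adjusted over the list alone; camera adjusted p = 8.5e-05; adjusted p = 0.074 with an estimated correlation). UBE2C (0.60 ± 0.07), the kinase AURKA (0.53 ± 0.05), HMMR (0.52 ± 0.06) and cyclin B1 CCNB1 (0.48 ± 0.06) rose. Replication-dependent histones fell in 7 of 13 and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0074; adjusted p = 0.17 with an estimated correlation). The linker histone H1-2 (-1.16 ± 0.16) and H2BC12 (-0.79 ± 0.13) fell. Markers of other cell types had no camera call with control siRNA, while fry called 3 of the 4 lists upward. Epithelial markers had 3 of 7 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.12, fry adjusted p = 0.00086), and smooth muscle markers 4 of 10 higher and 2 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.15, fry adjusted p = 0.00030). Endothelial markers had 2 of 7 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.57, fry adjusted p = 0.017), with a median of -0.19 and a mean of 0.30, and leukocyte markers had 1 of 3 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.74, fry adjusted p = 0.21).

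Cholesterol synthesis genes fell in 15 of 24 and none rose (15 and 0 adjusted over the list alone; camera adjusted p = 9.6e-07; adjusted p = 0.074 with an estimated correlation). The sterol reductase TM7SF2 (-0.91 ± 0.09), the regulator SREBF2 (-0.52 ± 0.06) and lanosterol synthase LSS (-0.45 ± 0.05) fell. Interferon-stimulated genes fell in 13 of 25 and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.00066; adjusted p = 0.17 with an estimated correlation). IFI44 (-0.72 ± 0.08), IFIT1 (-0.65 ± 0.08) and STAT2 (-0.46 ± 0.07) fell and DDX58, the RNA sensor RIG-I, rose (0.45 ± 0.08). Hypoxia and HIF targets rose in 8 of 24 and fell in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 2.0e-05; adjusted p = 0.11 with an estimated correlation). The angiogenic factor VEGFA (1.06 ± 0.07), the vasodilator ADM (1.01 ± 0.08) and the glucose transporter SLC2A3 (0.90 ± 0.06) rose. Heat shock proteins rose in 10 of 19 and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.33 with an estimated correlation). HSPH1 (0.68 ± 0.05), HSP90AB1 (0.53 ± 0.05) and HSPD1 (0.45 ± 0.06) rose and HSPA1B, which has a near-identical copy, fell by 0.45. With control siRNA 4647 genes (35.3%) passed the edgeR test, 2349 higher and 2298 lower (50.6% higher), and 460 changed at least 2-fold, 277 higher and 183 lower. On the deposited FPKM scale (pseudocount 1) the split was 1527 higher and 3096 lower (33.0% higher), with 33.2% and 34.1% under the other FPKM settings. The median log2 fold change over the genes tested was -0.068 with FPKM (pseudocount 1), against -0.0081 in the edgeR fit.

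The fourth comparison asked what H2O2 changed in cells with EP300 siRNA. GDF15 rose from 1.97 ± 0.05 to 38.2 ± 8.11 CPM (log2 fold change 4.27 ± 0.17), IL24 from 1.07 ± 0.21 to 14.9 ± 1.12 CPM (3.79 ± 0.16) and IL1B from 4.83 ± 0.58 to 44.7 ± 3.98 CPM (3.21 ± 0.12). SERPINB2 (2.87), the interleukin IL11 (2.80), the chemokine CXCL1 (2.77), KRTAP2-3 (2.56) and TGM2 (2.41) rose too, all 8 with edgeR adjusted p of 3.4e-08 or lower. Lower genes were PTPRQ, a phosphatase-family receptor (-2.41 ± 0.22), the complement gene C4B (-2.26 ± 0.17), whose reads cannot be assigned with certainty against its copy C4A, INHBE (-2.21 ± 0.14) and MAP2K6 (-2.08 ± 0.17). TMEM255A (-2.03), the amino acid transporter SLC38A4 (-1.76), TMEM143 (-1.63) and OLFML3 (-1.59) completed the 8, with edgeR adjusted p of 4.1e-06 or lower.

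NF-kB inflammatory targets rose in 17 of 23 and none fell in EP300 siRNA cells (18 and 0 adjusted over the list alone; camera adjusted p = 2.7e-30, 0.00013 with an estimated correlation). TNFAIP3 (1.35 ± 0.07) rose beside IL1B, IL11 and CXCL1. Of 25 p53 targets 17 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 1.5e-27, 0.00013 with an estimated correlation), CDKN1A by 2.07 ± 0.08, BTG2 by 1.66 ± 0.09 and AEN by 1.43 ± 0.06. Immediate early genes rose in 21 of 28 and none fell (22 and 0 adjusted over the list alone; camera adjusted p = 3.3e-26, 0.0072 with an estimated correlation). FOSL1 (2.19 ± 0.09), DUSP6 (1.74 ± 0.07), DUSP5 (1.71 ± 0.08) and DUSP4 (1.43 ± 0.06) rose. Senescence-associated secreted factors rose in 18 of 28 and fell in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 8.6e-18, 0.012 with an estimated correlation). TGF-beta and YAP targets rose in 14 of 24 and fell in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 2.1e-13, 0.0073 with an estimated correlation). ANKRD1 (2.14 ± 0.08), F3 (1.38 ± 0.06) and CCN2 (1.27 ± 0.09) rose. Apoptosis regulators rose in 12 of 30 and fell in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00070, 0.012 with an estimated correlation). The death receptors FAS (1.43 ± 0.09) and TNFRSF10B (0.59 ± 0.06), the inhibitor BIRC3 (0.93 ± 0.09) and BID (0.75 ± 0.08) rose.

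Cholesterol synthesis genes fell in 20 of 24 and none rose (21 and 0 adjusted over the list alone; camera adjusted p = 5.0e-15, 0.012 with an estimated correlation). INSIG1 (-1.17 ± 0.08), the sterol reductase DHCR7 (-0.78 ± 0.06) and SREBF2 (-0.64 ± 0.06) fell. Replication-dependent histones fell in 7 of 13 and none rose (8 and 0 adjusted over the list alone; camera adjusted p = 7.8e-05; adjusted p = 0.066 with an estimated correlation). H1-2 (-1.33 ± 0.17), H2BC21 (-1.28 ± 0.17), H2AC6 (-1.23 ± 0.20) and H2BC12 (-0.96 ± 0.12) fell. Extracellular matrix and fibroblast markers fell in 13 of 28 and rose in 5 (16 and 6 adjusted over the list alone; camera adjusted p = 7.8e-05; adjusted p = 0.26 with an estimated correlation). The collagens COL3A1 (-1.25 ± 0.13) and COL1A1 (-0.56 ± 0.05), LUM (-1.02 ± 0.08) and SPARC (-0.42 ± 0.04) fell. DNA replication genes fell in 11 of 38 and rose in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.046; adjusted p = 0.45 with an estimated correlation). These counts were 18 and 6 with each library's trend on length and GC content removed. MCM6 (-0.42 ± 0.05), MCM5 (-0.41 ± 0.05) and the transcription factor E2F1 (-0.38 ± 0.07) fell. Smooth muscle markers rose in 3 of 10 and fell in 2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.047; adjusted p = 0.14 with an estimated correlation). The actin ACTA2 (1.74 ± 0.13), SMTN (0.78 ± 0.07) and TAGLN (0.35 ± 0.08) were higher and LMOD1 (-0.46 ± 0.09) was lower. Epithelial markers had 3 of 7 higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.080, fry adjusted p = 0.0013). Endothelial markers had 1 of 7 higher and 2 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.51, fry adjusted p = 0.045 downward; median 0.10, mean -0.13), and leukocyte markers 1 of 3 higher and 0 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.35, fry adjusted p = 0.018 upward; median -0.13, mean 0.13). With EP300 siRNA 4095 genes (31.1%) passed the edgeR test for H2O2, 2100 higher and 1995 lower, and 354 changed at least 2-fold, 179 higher and 175 lower. With deposited FPKM (pseudocount 1) the majority turned, with 1718 higher and 2113 lower (44.8% higher against 51.3%). The median log2 fold change over the genes tested was -0.021 with FPKM, against -0.00038 in the edgeR fit.

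H2O2 effects with control and with EP300 siRNA, which share no library, correlated across genes at 0.66 (Pearson) and 0.68 (Spearman). The slope of the second on the first was 0.61. Noise in the first effect lowers such a slope, so it is not a measure of a weaker H2O2 response. Called genes overlapped: 1372 were higher in both against 375 for independent lists, 1225 were lower in both against 348, and 21 and 16 were called in opposite directions. Of the 277 genes that H2O2 raised at least 2-fold with control siRNA, 266 had the same sign and 200 were called higher with EP300 siRNA. The interaction test called the response weaker for 61 and stronger for 3. Of the 183 lowered at least 2-fold, 174 had the same sign and 108 were called lower, and the interaction called 4 weaker and 1 stronger. These genes were chosen on control siRNA libraries that also enter the interaction, which favours weaker calls. Keeping genes of any count lowered the Pearson correlation to 0.26.

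**Figure D3:**
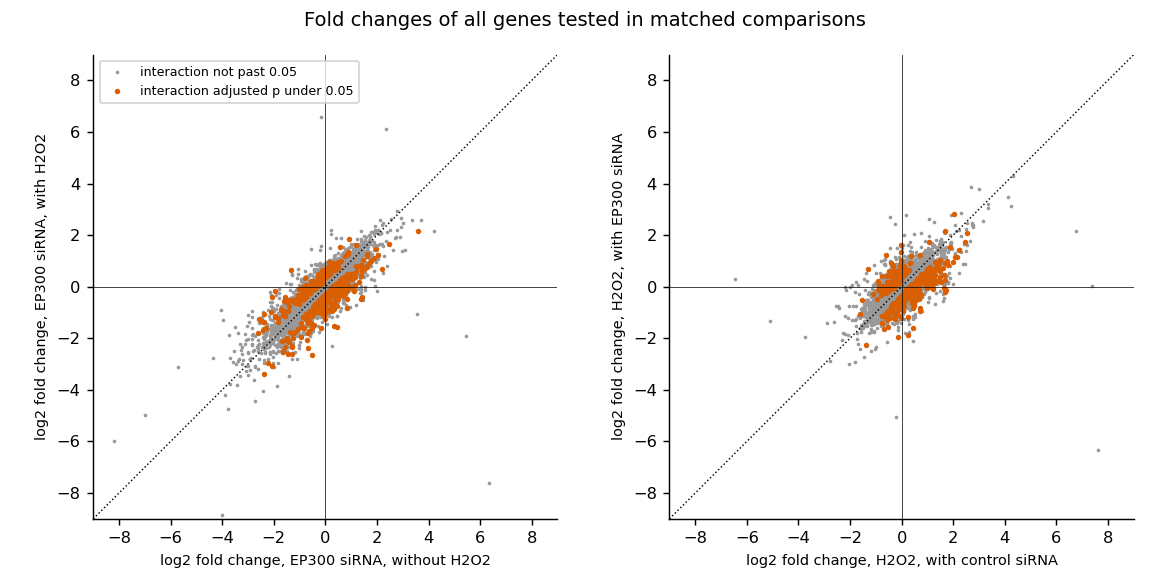
Log2 fold changes of the 13171 genes tested: EP300 siRNA effects with H2O2 against without (left) and H2O2 effects with EP300 siRNA against with control siRNA (right). Orange points are the 439 genes called by the interaction test; the Pearson correlations are 0.85 and 0.66.

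The interaction asked for which genes the EP300 siRNA effect differed between H2O2-treated and untreated cells, which equals a difference in the H2O2 response between the siRNAs. On the negative side PLAU, FBXO32, STC1 and BHLHE41 were raised by H2O2 with control siRNA and were not called for H2O2 with EP300 siRNA, and TCAF2 was raised with control siRNA and lowered with EP300 siRNA. PLAU, the urokinase plasminogen activator, went from 12.1 ± 0.56 to 37.8 ± 1.01 CPM with H2O2 in control siRNA cells and from 7.54 ± 0.75 to 7.29 ± 0.47 CPM in EP300 siRNA cells (log2 difference -1.69 ± 0.12, edgeR adjusted p = 1.2e-05). FBXO32, the muscle ubiquitin ligase atrogin-1, differed by -1.38 ± 0.15, the secreted hormone STC1 by -1.29 ± 0.17, the circadian repressor BHLHE41 by -1.28 ± 0.17 and TCAF2 by -1.26 ± 0.20 (edgeR adjusted p of 0.0028 or lower).

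On the positive side ATP6V0E2, a proton pump subunit, stood at 24.0 ± 2.63 and 17.99 ± 1.64 CPM without and with H2O2 in control siRNA cells and at 4.01 ± 0.65 and 7.52 ± 0.75 CPM in EP300 siRNA cells (log2 difference 1.32 ± 0.18, edgeR adjusted p = 0.0013), and RNF227 differed by 0.97 ± 0.14 (0.0015). ABHD14A differed by 1.17 ± 0.25 (edgeR adjusted p = 0.020), a call lost without siEP300 library 4 (0.077) or 5 (0.055) or siEP300.H2O2 library 11 (0.062) or 12 (0.063). PNMA8A differed by 1.06 ± 0.23 (edgeR adjusted p = 0.019), a call lost without siEP300 library 4 (0.053) or 5 (0.065), siNC.H2O2 library 8 (0.053) or siEP300.H2O2 library 11 (0.062). With unfiltered FPKM the PNMA8A difference was 0.61 and its call was lost (limma adjusted p = 0.068). SERPINF1 differed by 1.03 ± 0.27 (edgeR adjusted p = 0.0499), a call lost without siNC library 2 (0.10) or 3 (0.11), siEP300 library 4 (0.13) or 5 (0.11), siNC.H2O2 library 7 (0.055) or 8 (0.12), or siEP300.H2O2 library 10 (0.082), 11 (0.082) or 12 (0.16). That call was also lost with DESeq2 size factors (0.051) and limma-voom (0.067).

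Extracellular matrix genes were lower in 13 of 28 and higher in none in the interaction (19 and 1 adjusted over the list alone; camera adjusted p = 8.1e-21, 0.020 with an estimated correlation). Lysyl oxidase LOX (-1.03 ± 0.14), tenascin TNC (-0.82 ± 0.13), COL6A1 (-0.56 ± 0.08) and SPARC (-0.40 ± 0.06) were among them. Hypoxia and HIF targets were lower in 9 of 24 and higher in none (11 and 0 adjusted over the list alone; camera adjusted p = 6.1e-17, 0.017 with an estimated correlation). DDIT4, an mTOR inhibitor (-1.18 ± 0.14), and VEGFA (-0.85 ± 0.10) were lower beside LOX. Unfolded protein response and ATF4 targets were lower in 9 of 25 and higher in none (16 and 0 adjusted over the list alone; camera adjusted p = 2.6e-13, 0.040 with an estimated correlation). DDIT4, VLDLR (-1.003 ± 0.13), CHAC1 (-0.80 ± 0.15) and PSAT1 (-0.48 ± 0.09) were among them. Mitosis genes were lower in 7 of 30 and higher in none (14 and 0 adjusted over the list alone; camera adjusted p = 4.3e-11, 0.017 with an estimated correlation). The kinases PLK1 (-0.43 ± 0.08) and AURKA (-0.39 ± 0.07) and HMMR (-0.40 ± 0.08) were among them.

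DNA replication genes were higher in 8 of 38 and lower in none (27 and 0 adjusted over the list alone; camera adjusted p = 2.9e-18, 0.017 with an estimated correlation). RRM2 differed by 0.55 ± 0.07 and CCNE2 by 0.80 ± 0.13, the latter falling by 1.10 with H2O2 in control siRNA cells and by 0.30 in EP300 siRNA cells. NF-kB inflammatory targets were higher in 3 of 23 and lower in none (7 and 0 adjusted over the list alone; camera adjusted p = 0.00043, 0.040 with an estimated correlation). IL11 (0.78 ± 0.16, edgeR adjusted p = 0.015, and 0.052 without siEP300 library 5) was among them. Senescence-associated secreted factors were lower in 4 of 28 and higher in none (7 and 2 adjusted over the list alone; camera adjusted p = 0.00028; adjusted p = 0.33 with an estimated correlation), cholesterol synthesis genes lower in 4 of 24 and higher in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.33 with an estimated correlation), and TGF-beta and YAP targets lower in 3 of 24 and higher in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.028; adjusted p = 0.37 with an estimated correlation).

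Some of these list counts in the interaction moved by over 1.5 times under other settings, without a change in which direction had more members. With deposited FPKM (pseudocount 1) DNA replication genes were higher in 15 of 38, and NF-kB targets in 7 of 19, with a median of 0.31 against 0.20. With each library's trend on length and GC content removed, 21 DNA replication genes and 5 NF-kB targets were higher, and 16 mitosis genes, 14 unfolded protein response and ATF4 targets, 8 senescence-associated factors and 5 TGF-beta and YAP targets were lower. Without both libraries farthest out on the length axis, 25 DNA replication genes and 6 NF-kB targets were higher, and 17 mitosis genes, 14 hypoxia and HIF targets, 9 cholesterol synthesis genes and 7 TGF-beta and YAP targets were lower. Senescence-associated factors, with none called higher among 28, had 1 of 26 higher with deposited FPKM (pseudocount 1) and 2 of 28 without the far libraries.

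**Figure D4:**
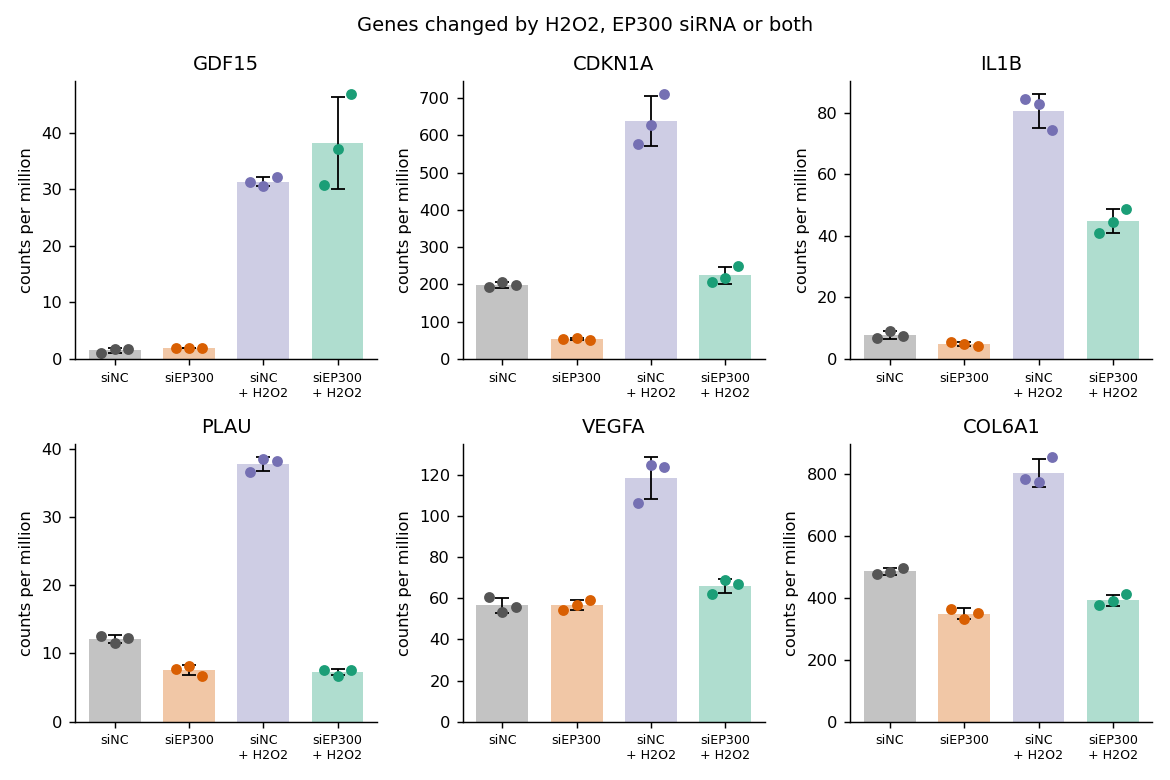
Levels in CPM of GDF15, CDKN1A, IL1B, PLAU, VEGFA and COL6A1 in each of the 12 libraries (points), with the mean (bars) and SD (error bars) of 3 libraries per group. H2O2 raised GDF15 by 4.34 and 4.27 on the log2 scale with control and EP300 siRNA, and PLAU was 37.8 CPM with control siRNA and H2O2 and 7.29 CPM with EP300 siRNA and H2O2.

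The interaction test called 439 genes (3.33%), 148 higher and 291 lower (33.7% higher), of which 51 differed at least 2-fold, 12 higher and 39 lower. At an unadjusted p under 0.05 there were 2221, and DESeq2 called 617. On the deposited FPKM scale (pseudocount 1) the split was 302 higher and 223 lower (57.5% higher), with 58.0% and 55.1% under the other FPKM settings. FPKM values were not scaled further between libraries. Their median log2 difference over the genes tested was 0.041 (pseudocount 1), against -0.00082 in the edgeR fit. The count was 681 without siNC library 1, 252 without 2 and 234 without 3. It was 196, 236 and 212 without siEP300 libraries 4, 5 and 6. It was 709 without siNC.H2O2 library 7 and 232 without 8, and 227 and 248 without siEP300.H2O2 libraries 11 and 12. It was 1996 with both libraries farthest out on the length axis left out and 1183 with each library's trend on length and GC content removed.

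The H2O2 effect with control siRNA and the EP300 siRNA effect with H2O2 share the siNC.H2O2 libraries with opposite signs. Their correlation across genes was -0.079 (Pearson) and -0.053 (Spearman), against -0.51 and -0.47 for simulated unchanged groups. Simulated fold changes hold only noise and spread less than the real ones, so these correlations cannot be compared in size. A covariance is not divided by that spread. The covariance was -0.0221 against a simulated -0.0140, a difference of -0.0081. Genes raised by H2O2 and lowered by EP300 siRNA numbered 942 against 719 for independent lists, genes moved the opposite way 704 against 653, genes raised by both 635 against 667, and genes lowered by both 735 against 704. The siNC.H2O2 group has 3 libraries and cannot be divided into parts of at least 2, so part of the excess may come from the shared libraries.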

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

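Tests chosen only after the result was seen were the removal of the trend on length and GC content, the fit without the pair of libraries farthest out on the length axis, the relation of corrected EP300 to the length slope, and the breakdown of the regroupings. The results of this part drew attention because the interaction test called a difference between the EP300 siRNA effect with and without H2O2. Groups of 3 libraries are too small for a test of single outlying libraries.

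For gene lists the median difference, with minus without H2O2 on the log2 scale, was -0.43 for extracellular matrix and fibroblast markers, -0.24 for hypoxia and HIF targets, -0.24 for unfolded protein response and ATF4 targets, -0.23 for mitosis, -0.14 for cholesterol synthesis, -0.12 for TGF-beta and YAP targets and -0.10 for senescence-associated secreted factors. It was 0.25 for DNA replication and 0.20 for NF-kB inflammatory targets. With a correlation estimated per list, camera did not call cholesterol synthesis (adjusted p = 0.33), TGF-beta and YAP targets (0.37) or senescence-associated secreted factors (0.33).

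Among secreted and matrix genes the log2 difference was -1.69 for PLAU, -1.29 for STC1, -1.03 for LOX, -1.03 for ADAMTS15, -0.82 for TNC, -0.79 for COL4A1, -0.62 for PDGFRB, -0.56 for COL6A1, -0.44 for COL6A2, -0.42 for TGFBI, -0.40 for COL1A1 and -0.40 for SPARC. The complement gene C4B differed by -0.88 and SERPINF1 by 1.03. Among genes of hypoxia and glucose use it was -1.18 for DDIT4, -0.85 for VEGFA, -0.73 for CA9, -0.65 for NDRG1, -0.64 for ADM, -0.39 for SLC2A3 and -0.31 for LDHA. Among genes of amino acid and redox stress it was -1.003 for VLDLR, -0.80 for CHAC1, -0.80 for SLC7A11, -0.61 for SESN2, -0.48 for PSAT1 and -0.41 for ASNS.

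Among cell cycle genes the log2 difference was -0.49 for CCND1, -0.48 for PLK2, -0.43 for PLK1, -0.43 for KIF20A, -0.40 for HMMR, -0.39 for AURKA and -0.38 for CCNB1, and it was 0.80 for CCNE2, 0.55 for RRM2, 0.39 for GINS1, 0.26 for CDC6 and 0.25 for RRM1. Among sterol genes it was -0.57 for INSIG1, -0.37 for DHCR7 and 0.78 for TM7SF2. Among genes of inflammation, heat shock, signalling and chromatin it was 0.78 for IL11, 0.64 for HSPA4L, 0.59 for BIRC3, 0.52 for RELB, 0.47 for ANKRD1, 0.37 for HDAC1 and -0.74 for DUSP6. The other genes were ATP6V0E2 (1.32), ABHD14A (1.17), PNMA8A (1.06), RNF227 (0.97), SYNPO (0.55), FBXO32 (-1.38), BHLHE41 (-1.28), TCAF2 (-1.26), SLC12A8 (-0.98) and TMEM143 (-0.96).

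Some of these calls were lost when 1 library was left out or under another setting. RELB was lost without siNC library 2 (edgeR adjusted p = 0.12) or 3 (0.11), siEP300 library 4 (0.15), 5 (0.054) or 6 (0.14), siNC.H2O2 library 8 (0.085) or 9 (0.097), or siEP300.H2O2 library 11 (0.10) or 12 (0.13), and also with limma-voom (0.056) and unfiltered FPKM (0.054). BIRC3 was lost without siNC library 3 (0.064), siEP300 library 4 (0.065) or 5 (0.064), siNC.H2O2 library 8 (0.064) or siEP300.H2O2 library 12 (0.054). GINS1 was lost without siNC library 2 (0.051), siEP300 library 4 (0.067) or 6 (0.061), or siNC.H2O2 library 8 (0.052). CCNB1 was lost without siEP300 library 4 (0.056) or 6 (0.054) or siEP300.H2O2 library 11 (0.052), and IL11 without siEP300 library 5 (0.052). ABHD14A was lost without siEP300 library 4 (0.077) or 5 (0.055) or siEP300.H2O2 library 11 (0.062) or 12 (0.063), and PNMA8A without siEP300 library 4 (0.053) or 5 (0.065), siNC.H2O2 library 8 (0.053) or siEP300.H2O2 library 11 (0.062), or with unfiltered FPKM (0.068). SERPINF1 was lost without siNC library 2 (0.10) or 3 (0.11), siEP300 library 4 (0.13) or 5 (0.11), siNC.H2O2 library 7 (0.055) or 8 (0.12), or siEP300.H2O2 library 10 (0.082), 11 (0.082) or 12 (0.16), and also with DESeq2 size factors (0.051) and limma-voom (0.067).

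A technical source weighed for the interaction was the axis within groups that follows transcript length and GC content. Once each library's trend was removed, 98.86% of the 439 genes were still called and 1183 genes were called in all, which argues against that trend as the whole source of the calls. Of 100 regroupings of the H2O2 labels within each siRNA, the real one included, 6 called at least 439 genes and the highest other called 2492, so chance is not excluded by that count. All 5 others kept the real H2O2 grouping within 1 siRNA and therefore carry the H2O2 effect, a structure of the samples. The 84 that kept it within neither siRNA called 0 genes at the highest, but there the H2O2 effect widens the spread within groups. The regroupings therefore cannot decide on chance. A different H2O2 response in cells with EP300 siRNA stays open as a biological explanation. Lower EP300 and other effects of the siRNA cannot be told apart there. Differences in handling between cultures, which the labels do not describe, may stay open as well.

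The same axis was weighed for the spread of EP300 between libraries of 1 group, where log2 EP300 followed each library's length slope over 12 libraries within groups (Pearson r = 0.959, exact within-group permutation p = 0.00772; Spearman rho = 0.958, exact p = 0.0108; r = 0.93 without the 2 libraries farthest out). Removing the trend left 62.14% of the pooled within-group SD (0.211 before, 0.131 after; jackknife SE 11.04, 52.5% to 67.1% without 1 library), and so met the bound written beforehand for rejecting the axis, an SD above 50% of its value. That bound is not taken as rejecting it, since corrected EP300 still followed the length slope (r = 0.867, exact p = 0.0177). The EP300 transcript has 9587 bases, and the correction was incomplete for it. For EP300 the axis and other sources of spread cannot be told apart.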

How the results depend on the processing

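Tests chosen only after the data were seen were trend removal, the fit without the pair of libraries farthest out on the length axis, and Spearman correlation. No paired analysis was possible because replicate numbers are not shared between groups and the labels name no pairs.

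Counts of called genes stayed within 1.5 times their reported value under DESeq2, its size factors in edgeR, limma-voom, both count filters and the 3 FPKM settings. A 2-fold minimum left 1300 and 1240 genes for EP300 siRNA without and with H2O2, 460 and 354 for H2O2 with control and EP300 siRNA, and 51 for the interaction, a smaller number by construction. The interaction called 1183 genes with the trend removed, 434 of the 439 among them, and 1996 without the far libraries, 438 of the 439 among them. The spread between libraries fell with the trend removed, from a coefficient of variation of 6.72% to 4.68%. Leaving out 1 library gave 7260 to 8184, 7075 to 7599, 3598 to 4587, 3019 to 3923 and 196 to 709 genes in the 5 comparisons, with EP300 siRNA first. The interaction moved by over 1.5 times without siNC 1 (681), 2 (252) or 3 (234), siEP300 4 (196), 5 (236) or 6 (212), siNC.H2O2 7 (709) or 8 (232), or siEP300.H2O2 11 (227) or 12 (248).

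The fall of EP300 with its siRNA passed the threshold under each alternative, at -1.35 to -1.02 without and -1.62 to -1.22 with H2O2. Leaving out 1 library gave -1.30 to -1.03 and -1.61 to -1.33 for these, -0.25 to 0.03 and -0.46 to -0.36 for H2O2 with control and EP300 siRNA, and -0.43 to -0.15 for the interaction. Over all alternatives EP300 moved by -0.25 to 0.19 for H2O2 with control siRNA, so its sign was not settled. H2O2 with EP300 siRNA passed the threshold for EP300 without a filter (-0.40), with the trend removed (-0.31), with DESeq2 (-0.39), with FPKM and pseudocount 0.1 (-0.42), in only the 2 groups (-0.40) and without the far libraries (-0.40). The interaction for EP300 passed it without the far libraries (-0.59). The cause was not tested.

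The correlation of EP300 siRNA effects (0.85) was 0.46 without a filter, 0.91 with at least 50 counts, 0.90, 0.89 and 0.89 with FPKM at pseudocounts 1 and 0.1 and unfiltered, 0.89 with only the 2 groups and 0.80 without the far libraries. That of H2O2 effects (0.66) was 0.26, 0.77, 0.76, 0.74, 0.74, 0.74 and 0.57 under these alternatives, and 0.73 over genes called in either. The relation over shared libraries (-0.079) was -0.33 without a filter. Leaving out 1 library gave 0.83 to 0.86, 0.62 to 0.67 and -0.16 to -0.047. The filters differ in the genes included, and the cause of the other shifts was not tested.

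Over 130 list tests camera called 52, of which 33 lost their call with a correlation estimated per list and 19 kept it. Lost without H2O2 for EP300 siRNA were NRF2, mitosis, unfolded protein response, TGF-beta and immediate early genes (adjusted p = 0.29) and interferon genes (0.42). With H2O2 these were NRF2, DNA replication, interferon, hypoxia, TGF-beta and immediate early genes (0.39), glycolysis (0.52), unfolded protein response (0.61) and extracellular matrix (0.61). For H2O2 with control siRNA they were apoptosis (0.059), mitosis and cholesterol (0.074), hypoxia (0.11), interferon and histones (0.17), heat shock (0.33) and glycolysis (0.53). With EP300 siRNA they were histones (0.066), smooth muscle (0.14), heat shock and extracellular matrix (0.26), interferon (0.28), unfolded protein response (0.36) and DNA replication (0.45). In the interaction they were senescence and cholesterol (0.33) and TGF-beta (0.37). The cause was not tested. Fry, which does not compare a list with other genes, called 30 of the 78 tests that camera did not, and missed 1 that camera called, TGF-beta and YAP targets in the interaction (0.075). Among the 30 were, for EP300 siRNA without H2O2, apoptosis (6.1e-05), cardiomyocyte (3.3e-06) and acetyltransferase genes (0.00088), and with H2O2 cardiomyocyte (4.3e-06), acetyltransferase (0.0021) and endothelial genes (5.4e-06). The acetyltransferase list holds EP300 itself, the siRNA target.

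Across 270 results for named genes, 4685 of 4753 alternative values had the same call, 52 lost it in 11 results, 16 gained it and 0 reversed. Fits of only the 2 groups compared called 8225, 7283, 3448 and 5194 genes in the 4 two-group comparisons, with EP300 siRNA first. The fit to all libraries called more genes for H2O2 with control siRNA (4647) than with EP300 siRNA (4095), and this order reversed here. It also reversed without the far libraries (4886 and 5267). In each fit of only the 2 groups, 1 of the 10 splits of the 6 libraries, the real one, called as many genes, against 0 in the highest other. The 10 splits are too few for a share under 0.05.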

Other observations

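Tests chosen only after the result was seen were the search for words that mark lower and higher genes, the test of leading words on genes not used to choose them, the comparison of GGAGAA with other words, removal of the trend on length and GC content, and the fit without the pair of libraries farthest out on the length axis.

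Acetyltransferase and deacetylase genes, the family of EP300 and its opposing enzymes, went both ways with EP300 siRNA. The list holds EP300 itself, the siRNA target, which is counted among the lower genes in both EP300 siRNA comparisons. Without H2O2, 9 of 32 rose and 13 fell (9 and 13 adjusted over the list alone; camera adjusted p = 0.61), with the deacetylases HDAC9 (log2 fold change 1.45) and HDAC1 (0.89) higher and HDAC5 (-0.66) and the acetyl-lysine reader BRD2 (-0.73) lower. With H2O2, 8 rose and 13 fell (8 and 13 adjusted over the list alone; camera adjusted p = 0.71), with HDAC9 (1.55) higher and HDAC11 (-1.56) lower. Of the same 32 genes H2O2 raised 2 and lowered 5 with control siRNA (camera adjusted p = 0.28). Apoptosis regulators had 12 of 30 higher and 10 lower with EP300 siRNA (12 and 10 adjusted over the list alone; camera adjusted p = 0.56), and with deposited FPKM these counts were 10 and 12 of 29 and the median changed sign. Cytochrome c CYCS (0.91) and BCL2L1 (0.80) rose and the proapoptotic BMF (-2.34) fell. With control siRNA, H2O2 raised 14 apoptosis regulators and lowered 4 (15 and 4 adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.059 with an estimated correlation).

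Heat shock proteins rose in 10 of 19 and fell in 2 with H2O2 in EP300 siRNA cells (10 and 4 adjusted over the list alone; camera adjusted p = 0.0024; adjusted p = 0.26 with an estimated correlation), among them the chaperones HSPA4L (0.71), HSP90AA1 (0.60) and HSPH1 (0.46) and the cochaperone CHORDC1 (0.45). EP300 siRNA without H2O2 raised 7 and lowered 6 of them (camera adjusted p = 0.47; median -0.06, mean 0.04), and these counts were 7 and 8 of 18 with deposited FPKM, while the median was 0.06 with the trend removed. H2O2 in EP300 siRNA cells also lowered 8 of 25 interferon-stimulated genes and raised 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0046; adjusted p = 0.28 with an estimated correlation) and lowered 10 of 25 unfolded protein response and ATF4 targets and raised 7 (10 and 8 adjusted over the list alone; camera adjusted p = 0.0046; adjusted p = 0.36 with an estimated correlation). Glycolysis genes rose in 10 of 19 and fell in 3 with H2O2 in control siRNA cells (10 and 3 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.53 with an estimated correlation).

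Lists without a camera call for EP300 siRNA without H2O2 included the nuclear-encoded respiratory chain (6 of 30 higher, 7 lower; 6 and 6 adjusted over the list alone; camera adjusted p = 0.74; median -0.03, mean 0.0091; 13 higher and 6 lower with the trend removed), ferroptosis regulators (10 of 24 higher, 8 lower; 10 and 8 adjusted over the list alone; camera adjusted p = 0.65) and autophagy and lysosome genes (15 of 34 higher, 7 lower; 15 and 7 adjusted over the list alone; camera adjusted p = 0.36). Of the epithelial markers 3 of 7 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.47), and of the leukocyte markers 2 of 3 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.56). The list of mitochondrially encoded genes had 0 measured members. With H2O2, senescence-associated secreted factors split evenly with EP300 siRNA, 11 of 28 higher and 11 lower (13 and 11 adjusted over the list alone; camera adjusted p = 0.71), with a median of 0.14 (-0.05 with deposited FPKM, pseudocount 1), a mean of 0.12 and a camera direction downward. Mean and median also differed in sign for cardiomyocyte markers with H2O2 in control siRNA cells (median 0.04, and -0.05 without both libraries farthest out on the length axis; mean -0.14; camera adjusted p = 0.99).

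Short words in transcripts marked the genes that fell with EP300 siRNA. The 187 of 10751 genes with AGCGGAA in the 3′ UTR had a median log2 fold change of -0.21 without and -0.28 with H2O2, against 0.02 and 0.01 for the others, and the word led 15556 tested words in both comparisons (z of -10.06 and -9.96; family-wise permutation p = 0.001, the smallest the permutations can give). The leading word was also chosen on 1 part of the genes and tested on the remaining genes. It was AGCGGAA in 1 case and GCGGAAA in the other. On the remaining genes 0 of 137 other words made of the same bases marked genes as low in either comparison (z of -6.74 to -6.25 for the leading words). Words that hold the first or last 6 bases of the leading word, such as GCGGAAA for AGCGGAA, were not among the 137. The result argues against base composition. Silencing through a seed match by the EP300 siRNA is a candidate explanation, as a hypothesis, since the siRNA sequence is not given in the sources used here and all genes come from the same libraries. Matches to this word alone are argued against, since 58.68% of the 3277 genes lower in both comparisons carry no GCGGAA, against 72.45% of all genes, and effects of lower EP300 itself stay open.

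The share of genes called lower with EP300 siRNA without H2O2 was 26.7% with 0 GCGGAA words, 42.3% with 1, 51.7% with 2 and 52.9% with 3 or more. These shares, and the shares without GCGGAA given above, were not adjusted for transcript length or GC content. Fold changes in this comparison followed both, with rank correlations of 0.20 and -0.36 across genes. For AGCGGAA in coding sequences z was -14.17 without and -13.32 with H2O2. The word GCGGAA was present in 7 of the 12 genes named for the largest falls, in EP300 and in CDKN1A.

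Zinc finger genes of the ZNF family, mostly transcriptional repressors, were not among the lists fixed beforehand. With EP300 siRNA 210 of 439 rose and 60 fell without H2O2 (median log2 fold change 0.27 against -0.01 for other genes). With H2O2 230 rose and 53 fell (0.36 against -0.03). The share higher was 47.8% against 29.5% of other genes without H2O2, and 52.4% against 27.6% with it. With deposited FPKM (pseudocount 1) the medians were smaller, 0.13 against -0.06 without H2O2 (147 of 363 higher, 64 lower) and 0.23 against -0.02 with it (185 higher, 49 lower). With each library's trend on length and GC content removed, 87.28% of the first median was left, which argues against that trend as the whole source. Silencing of word carriers by the control siRNA was weighed with GGAGAA, part of the leading 3′ UTR word of higher genes. That word was AGGAGAA, which also led with ZNF genes left out, while CGGAGAA led in coding sequence. Across 430 ZNF genes, which are not independent replicates, the rise followed the number of GGAGAA words per kilobase (Spearman rho = 0.23, bootstrap 0.14 to 0.32, permutation p = 1e-05, the smallest that 100000 permutations can give). This met what was written beforehand for that explanation but is not taken as support, since other 6-base words followed the rise more closely (GAGAGA, rho = 0.497) and the shares of other words at least as close, 5.34% without and 2.62% with H2O2, 4.74% and 3.01% in coding sequence, and 4.03% and 5.84% in the 3′ UTR, lay on both sides of the 5% taken as a limit after the rho was seen. Silencing by the control siRNA and other properties of these genes that follow their sequence cannot be told apart, and lower EP300 stays open as a biological explanation.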
